A study of Homo sapiens with 8 samples.

How the data were processed

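The arrays were Affymetrix HG-U133A chips, 1 per sample, with 4 arrays of untreated PC-3 cells and 4 of cells given arachidonic acid (AA) for 2 h. The deposited values were linear probe set intensities, 1 per probe set and array, made by the authors with GCOS per the submitters' processing notes. The version of GCOS, its summary method and detection calls were not given in the sources used here. From the values, the authors had scaled each array to a trimmed mean (2% off each end) of 250 for the arrays with numbered titles and 500 for those with the word final in the title. Groups and titles came from the submitters' labels. The array run records, as deposited, gave each array's scan date, chip lot, scanner and fluidics protocol, and served to sort arrays into 3 scan dates and to compare how they were processed. The record of array B, the only untreated array of the final set, lists another fluidics protocol than C and D, with 0 first wash cycles and a first stain of 0 s, against 10 cycles and 600 s for every other array.

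Each array was rescaled to a trimmed mean of 500, an offset of 32 was added, and log2 was taken, so a fold change is on the log2(signal + 32) scale and understates the change of dim genes. A probe set was tested where at least 4 of the 8 arrays reached a signal of 100. The 68 control probe sets were left out. Of 22283 probe sets, 19065 listed 1 gene symbol, 1043 several, and 2107 were not listed in the platform annotation used here. Symbols were updated through Entrez gene identifiers with RefSeq's GRCh38.p14 gene table, which matched 19053. Probe sets with several symbols or none listed are given by their identifier. No genome build was given in the sources used here, so no coordinates are printed. After the filter 14237 probe sets remained, 12617 of them with 1 symbol, for 8664 distinct genes. The median gene shifted by less than 0.1 on the log2 scale under each scaling (-0.03 scaled, -0.01 quantile normalized, -0.03 as deposited).

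AA was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) over all 8 arrays, with the title set as a block because the sets hold 3 and 1 untreated and 2 and 2 AA arrays. The difference between title sets came from the same fit, and the interaction of AA with title set from a fit with that term. Arrays 1 and 1a were to be averaged only if they differed by an SD under 50% of the smallest among other pairs of one set and group, which they did not. Signals are given as mean ± SD over arrays and log2 changes with limma's SE.

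The gene lists were fixed before the data were examined: 23 lists with 565 distinct genes, of which 500 were named on the array. They covered NF-kB targets, immediate-early genes, eicosanoid metabolism, PPAR targets with fatty acid oxidation, fatty acid synthesis, sterol synthesis, PI3K pathway components, FOXO targets, ATF4 and unfolded protein response, NRF2, heat shock, metallothioneins, hypoxia with glycolysis, S phase, mitosis, interferon, cAMP and CREB targets, ribosomal proteins, epithelial genes of PC-3 cells, luminal prostate genes, and fibroblast, leukocyte and endothelial markers. Each gene was represented by its probe set with the highest mean, and list counts come from a limma fit over these 8664 genes. Lists with at least 3 measured genes (22) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. camera compares a list with the other genes, while fry tests whether its genes move one way. The SE of a list's mean comes from the 8 array means with the same block.

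Genes were named by a rule fixed before the data were examined: up to 12 rises and 12 falls with the largest changes past the threshold and the same sign in both title sets, 1 probe set per gene, or the 12 smallest p in a direction where fewer than 5 passed; every panel gene with a probe set; and up to 4 members of each list with the smallest p, of which 4 were followed for called lists and 2 or fewer for the others. Members named further to show a list's spread were chosen after their values were seen.

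The steps were tested on simulated arrays drawn with the means of the real ones and limma's moderated variances. This was done for the comparison of AA with untreated with the title set block, over 13811 probe sets. Of 95 probe sets changed by 1 on the log2 scale 76.8% were recovered, and all 93 changed by 2, with 8 false calls among 174. With 174 calls, against 19 in the real data, the adjusted threshold was looser, so recovery in the real data may be lower. A simulated list shifted by 0.5 was called and no other list was. Residuals were drawn independently between probe sets or genes and without a scan date difference. In the real data the estimated correlation reached 0.91 in the interferon list. The simulation therefore does not show how often camera calls correlated lists without a true shift.

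Alternatives fixed in advance were no block, the title set as a random block, quantile normalization, values as deposited, offsets of 8 and 100, no filter and a floor of 200, trended and robust variances, array weights, arrays 1 and 1a averaged, each title set alone, leaving out each array, estimated correlation, fry, and the mean of a gene's probe sets. Scan date as a block and the first scan date alone were added after the data were examined. Figures were drawn with matplotlib in Python.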

Results

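Messenger RNA was measured in PC-3 cells, a line derived from a bone metastasis of human prostate cancer, that were left untreated or given arachidonic acid (AA) for 2 h. Arachidonic acid is the omega-6 fatty acid from which cells make prostaglandins and leukotrienes. It was given at 5 µg/mL in medium with 0.25 mg/mL albumin, and untreated cells received albumin alone. The description calls untreated cells 0 hr, as do the titles of arrays 1, 1a and 2, while the title of array B names no time. The labels do not state whether untreated cells were kept for 2 h. The question named by the submitters is which genes the fatty acid induces in these cells, alongside its effect on PI3K signalling. Each group had 4 Affymetrix HG-U133A arrays, so the number of arrays limits the precision. The untreated arrays are called 1, 1a, 2 and B and the AA arrays 3, 4, C and D, after their titles. The labels do not say that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

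The arrays fell into sets. Arrays 1, 1a, 2, 3 and 4 carry numbered titles, and B, C and D carry titles with the word final. The run records show 3 scan dates: arrays 1, 2, 3 and 4 on one, array 1a alone on another, and arrays B, C and D on the last. The first principal component held 58.6% of the variance and placed arrays 1, 2, 3 and 4 on one side and 1a, B, C and D on the other. Array 1a correlated more closely across probe sets with the final arrays (mean Pearson r = 0.947) than with the 4 arrays of the first date (mean r = 0.904), which correlated with one another at a mean of 0.963. Arrays 1 and 1a differed by an SD of 0.70 on the log2 scale, against 0.33 for the closest other pair of one set and group, and were kept as 2 samples. The comparison of AA with untreated cells carried the title set as a block. Values with scan date as the block, chosen after the data were examined, stand beside it for the lists and genes where they are named. The scan date block gives array 1a no weight in the AA effect, because that array has no AA partner on its date.

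Several chemokine genes and other NF-kB target genes rose with AA. CXCL2, CXCL3 and CXCL1, neighbouring members of the family of chemokines that attract neutrophils, had the largest increases of any named gene. CXCL2 was read by 209774_x_at, and whether the probe sets of these related genes share signal was not tested. The CXCL2 signal went from 232 ± 136 (SD, n = 4) in untreated cells to 6231 ± 1815 (SD, n = 4) with AA, a log2 change of 4.94 ± 0.26 (SE). CXCL3 changed by 4.85 ± 0.20 and CXCL1 by 4.36 ± 0.17, the latter from 404 ± 99.9 to 8246 ± 2067 (SD, n = 4). CXCL8, which encodes interleukin 8, rose by 3.26 ± 0.20 and 3.57 ± 0.22 in its 2 probe sets. CCL20, a chemokine for dendritic cells and lymphocytes, rose by 3.04 ± 0.23 from a signal of 19.5 ± 6.64 (SD, n = 4), where the offset of 32 added before taking logs understates the change.

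NFKBIA and TNFAIP3 rose as well. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, rose by 3.12 ± 0.18 (SE) to a signal of 9800 ± 1486 (SD, n = 4), and TNFAIP3, the ubiquitin-editing enzyme A20, by 2.49 ± 0.24 (202644_s_at), while its other probe set 202643_s_at changed by 1.60 ± 0.26 and did not pass. The remaining increases were PLAU, the urokinase plasminogen activator (1.99 ± 0.19), the adhesion molecule ICAM1 (1.86 ± 0.16 and 1.59 ± 0.16 in 2 probe sets, and 0.92 ± 0.20 in 215485_s_at, which did not pass), the cytokine LIF (1.47 ± 0.16) and COQ4, which takes part in coenzyme Q synthesis (1.16 ± 0.16). In all, 19 of 14237 tested probe sets passed limma's test after Benjamini-Hochberg adjustment, 17 higher and 2 lower with AA. Adjusted p for the 11 named genes that rose ran from 8.84e-06 for CXCL1 to 0.0338 for COQ4 in limma. COQ4, whose signal with AA was the lowest of these genes (153 ± 38.3, SD, n = 4), lost its call without array 1, B, 3, 4, C or D (adjusted p from 0.102 to 0.328 by limma), with trended, robust variances (0.207), without the filter (0.0809) and with an offset of 100 (0.0779). LIF lost its call without array B or 3 (0.0921 and 0.0582), and the PLAU probe set 205479_s_at without B (0.0655). With no block, TNFAIP3 202644_s_at (adjusted p = 0.0563 by limma), ICAM1 202637_s_at (0.186), LIF (0.253) and COQ4 (0.646) lost theirs. COQ4 also lost it with the title set as a random block (0.0779). The 3 probe sets without a single gene symbol in the annotation also rose: 210229_s_at by 4.33, 218810_at by 2.75 and 210538_s_at by 2.24. The scan date block gave 31, among them all 19. Without array B 12 passed and without array 1a 31.

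**Figure D1:**
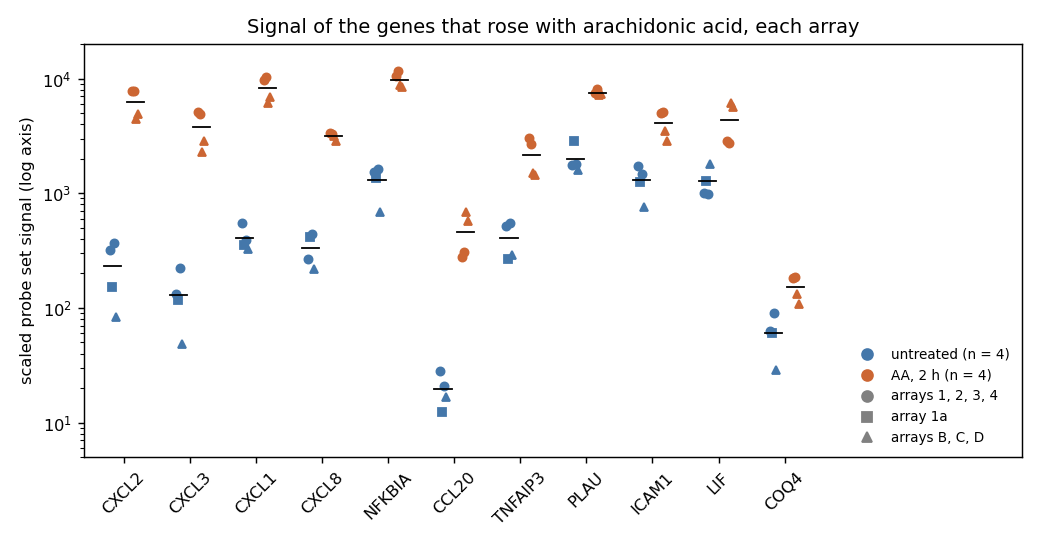
Scaled probe set signal (log axis) of the 11 named genes that rose with AA, 1 point per array, coloured by group and shaped by scan date, with a bar at the mean of 4 arrays. The AA arrays lie above the untreated arrays for each gene, and CCL20 rises from a mean of 19.5 to 461.

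The list of NF-kB target and inflammatory genes moved upward as a group. Its 28 measured genes had a mean log2 change of 1.59 ± 0.13 (SE over arrays), and 25 of them were higher with AA. By limma, 10 members rose over all genes tested and 23 rose adjusted over the list alone; none fell in either. Members that rose only by the second count included IER3 (1.26 ± 0.18), IL1B (2.07 ± 0.40), IL6 (1.64 ± 0.30) and IRF1 (1.71 ± 0.33). The subunit genes NFKB1 (0.51), NFKB2 (0.52) and RELB (0.60) were also among them, while RELA changed by -0.02 and TNF by -0.12 and neither passed. This was the only list of 22 that limma's camera called with an estimated correlation between genes (adjusted p = 0.0093) and the only one called by fry (adjusted p = 3.0e-04). Under the scan date block fry also called the immediate-early list (adjusted p = 0.0035) and the ATF4 and unfolded protein list (adjusted p = 3.2e-04). In a permutation over the 35 splits of the 8 arrays into 4 and 4, no other split gave a mean change as large. The two-sided permutation p was 0.0286, the smallest 35 splits allow, and 0.314 after adjustment over the 22 lists. For the NF-kB list the largest mean of another split was 1.18. The leukocyte list, lower with AA, gave the same p before and after adjustment. These splits mix title sets and scan dates, whose arrays are not freely exchangeable, so the p is approximate. Within scan dates there are 18 assignments. The scan date block gave a mean of 1.498 ± 0.0763, and 15 members rose over all genes tested.

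**Figure D2:**
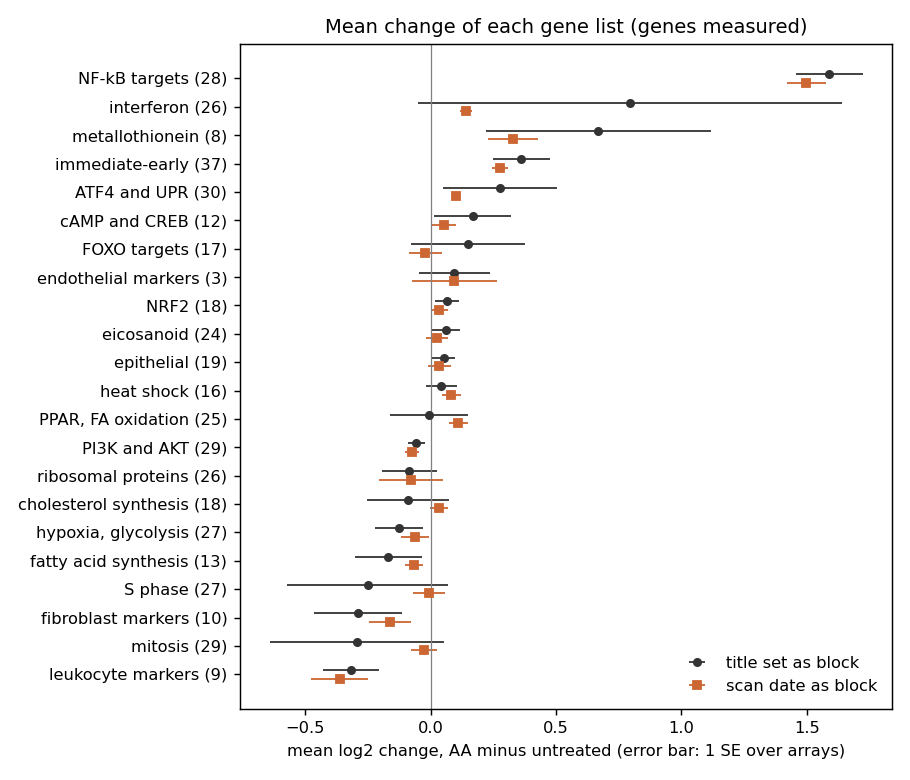
Mean log2 change with AA of each tested gene list, with the number of measured genes in parentheses. Circles use the title set as block and squares the scan date, and error bars are 1 SE over arrays. The NF-kB targets stand at 1.59 and 1.498, while the interferon list moves from 0.79 to 0.14.

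Immediate-early genes, which growth factors and stress switch on within minutes to hours, were higher by a mean of 0.36 ± 0.11 (SE over arrays), with 30 of 37 measured genes above 0. None passed over all genes tested, and 5 rose adjusted over the list alone: IER3, JUNB (1.04 ± 0.20), SGK1 (1.41 ± 0.29), IER5 (0.94 ± 0.20) and JUN (0.63 ± 0.17). IER3 is also a member of the NF-kB list. The list was called by camera with its preset correlation, but not with an estimated one (adjusted p = 0.131). Blocked by scan date, its mean was 0.28 ± 0.03, fry called it, an estimated correlation did not (adjusted p = 0.0514), and IER3 rose over all genes tested. EGR1 differed by -0.47 ± 0.34 in 201693_s_at and by -0.65 ± 0.20 in 201694_s_at, and MYC by 0.13 ± 0.31, and none of these passed. SGK1 changed by 0.70 within the first scan date and by 2.36 within the final set, and by 0.89 over all arrays without B. MYC changed by 0.72 within the first scan date and by -0.12 within the final set. FOS stayed below the filter, with a highest signal of 116.

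Lists tied to the metabolism of arachidonic acid and other lipids were not called. The 24 measured genes of eicosanoid synthesis, breakdown and receptors had a mean change of 0.06 ± 0.06 (SE over arrays) and a median of -0.04. Of these, 2 rose adjusted over the list alone and none over all genes tested. PTGS2, the inducible cyclooxygenase that commits arachidonic acid to prostaglandins, went from a signal of 57.6 ± 13.2 to 144 ± 6.16 (SD, n = 4), a log2 change of 1.00 ± 0.15 (limma, adjusted p = 0.0687 over all probe sets). PTGS2 passed with the scan date block (1.07 ± 0.13, adjusted p = 0.0208 by limma). AKR1C3, a reductase of prostaglandins and steroids, changed by 0.53 ± 0.14. The 25 genes of PPAR targets and fatty acid oxidation had a mean of -0.01 ± 0.15 (0.11 ± 0.04 with the scan date block, not called), among them PLIN2 at 0.23 ± 0.21, CPT1A at 0.08 ± 0.22, PDK4 at -0.54 ± 0.25 and ANGPTL4 at 0.01 ± 0.33. Genes of fatty acid synthesis had a mean of -0.17 ± 0.13, all 13 lying below 0 without passing, but -0.07 ± 0.04 with the scan date block, where 6 of 13 lay above 0. Genes of sterol synthesis had a mean of -0.09 ± 0.16, which turned to 0.03 ± 0.04 with the scan date block. Among the latter, SREBF2 differed by -0.46 ± 0.18.

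For PI3K signalling the arrays give transcript levels only. The 29 measured genes encoding components of the PI3K, AKT, mTOR and IKK pathways had a mean change of -0.06 ± 0.03 (SE over arrays), and none passed in either count. PIK3CD differed by -0.77 ± 0.24 and AKT2 by -0.42 ± 0.18. The 17 measured FOXO targets, which AKT activity represses, had a mean of 0.15 ± 0.23 with the title set block and -0.02 ± 0.07 with the scan date block.

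Other lists that camera called with its preset correlation had smaller support. Interferon-stimulated genes had a mean change of 0.79 ± 0.85 (SE over arrays), metallothioneins 0.67 ± 0.45 and genes of the ATF4 and unfolded protein response 0.28 ± 0.23. Mitosis genes stood at -0.29 ± 0.35, S-phase genes at -0.25 ± 0.32 and cAMP and CREB targets at 0.17 ± 0.15. None of their members passed over all genes tested, and adjusted over the list alone only IRF1 and MT1H (0.71 ± 0.19) rose. With an estimated correlation their adjusted p ranged from 0.533 to 0.718. The level of these lists differed between scan dates: the interferon list was higher by 3.55 on arrays 1, 2, 3 and 4 than on the others, and the mitosis list lower (difference -1.36). Under the scan date block the means were 0.14 ± 0.02 for interferon, 0.33 ± 0.10 for metallothioneins and 0.10 ± 0.007 for ATF4 targets (SE over arrays). Those of mitosis (-0.03 ± 0.05), S phase (-0.01 ± 0.06) and cAMP targets (0.05 ± 0.05) lay near 0. Of these, camera with its preset correlation called metallothioneins (adjusted p = 6.9e-04) and ATF4 targets (adjusted p = 0.0115) under that block, but not with an estimated correlation (adjusted p = 0.229 and 0.183). fry called the ATF4 targets there and not the metallothioneins (adjusted p = 0.062).

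**Figure D3:**
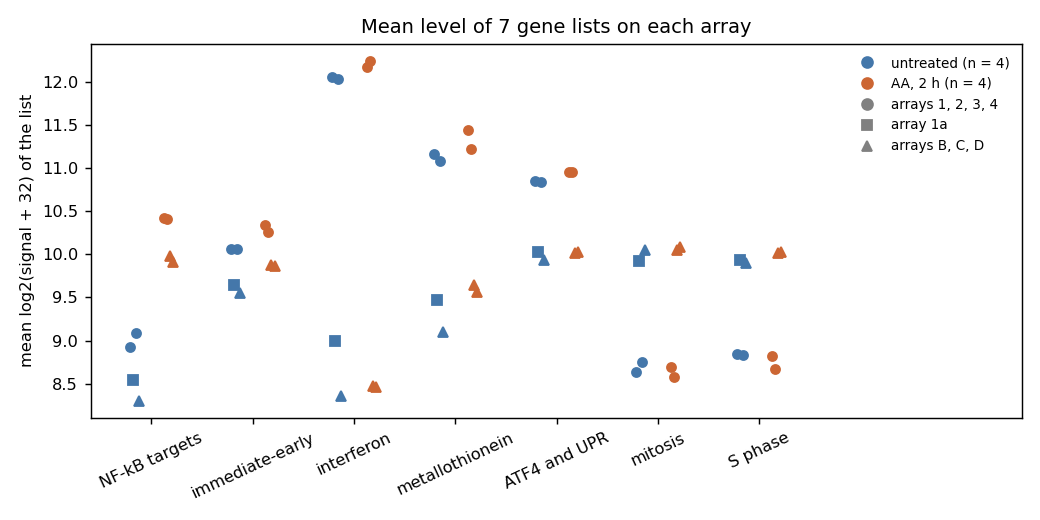
Mean log2(signal + 32) of 7 gene lists on each array, coloured by group and shaped by scan date. The NF-kB list separates the groups, while the interferon list is 3.55 higher on arrays 1, 2, 3 and 4 than on the others, whatever the group.

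The lists for NRF2 targets (mean change 0.07), heat shock proteins (0.04), hypoxia and glycolysis (-0.13) and ribosomal proteins (-0.08) were not called. The adjusted p of all 12 uncalled lists by camera ran from 0.0924 to 0.734.

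Markers of other cell types did not rise with AA. Leukocyte markers were lower by a mean of -0.32 ± 0.11 (SE over arrays, 9 measured genes) and fibroblast markers by -0.29 ± 0.18 (10 genes). Both lists were called with the preset correlation but not with an estimated one (adjusted p = 0.533 for each), and THY1 (-0.57 ± 0.16) was the only member to fall adjusted over its list alone. The fibroblast list lost its call with scan date as the block (mean -0.16, adjusted p = 0.3004), where the leukocyte list kept it (mean -0.36, adjusted p = 0.0148). The leukocyte list lost its call without array B (mean -0.20, adjusted p = 0.244), with values as deposited (-0.11, 0.256) and with a floor of 200 (-0.12, 0.397). Most leukocyte markers were dim, such as MS4A1 at 188 ± 37.7 and CD3D at 154 ± 33.5 (SD, n = 4) in untreated cells. The mean of the 3 endothelial markers was 0.09 ± 0.14 and that of the 19 epithelial and mesenchymal genes typical of PC-3 cells 0.05 ± 0.05 (median -0.03), where PLAU was the one member that rose. The list of androgen receptor and luminal prostate genes had 1 measured member, TMPRSS2, and was not tested. KLK3, which encodes prostate-specific antigen, had a highest signal of 165.

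Few genes were lower with AA, and those were dim. CD5, a surface receptor known from lymphocytes, fell by 1.13 on the log2 scale (SE 0.14, adjusted p = 0.0173 by limma), from a signal of 240 ± 55.2 to 107 ± 36.4 (SD, n = 4). The CEACAM5 probe set 217291_at, for the carcinoembryonic antigen gene, fell by 1.13 as well (SE 0.15, adjusted p = 0.0338 by limma), from 125 ± 17.2 to 39.4 ± 6.38 (SD, n = 4), while the gene's brighter probe set 201884_at differed by -0.28 ± 0.14 and did not pass. Neither fall passed in limma with trended, robust variances (adjusted p = 0.0555 for CD5 and 0.409 for CEACAM5). Each also lost its call without array 1, 2, B, 3, 4, C or D, and kept it without 1a. The next smallest p-values among lower probe sets did not pass: KLF6 (211610_at, -1.13 ± 0.18), SEMA6A (-0.74), ACTG2 (-0.86), GJB1 (-0.70), FOXA2 (-0.92), AJAP1 (-1.36), HIPK3 (-0.82), SCD5 (-0.88), LDHC (-0.92) and DHX9-AS1 (-0.68). KLF6 211610_at passed with the scan date block (-1.22 ± 0.16, adjusted p = 0.0344 by limma), while the other 2 KLF6 probe sets were higher, at 0.63 and 0.78, without passing. Among probe sets with an unadjusted p under 0.001, the 40 higher ones had a median signal of 696 and the 9 lower ones 154, against 413 for all tested.

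A panel of 24 genes tied to arachidonic acid, NF-kB and fatty acid response had been fixed before the data were examined. Of these, 19 had a tested probe set, LTA and FOS were below the filter, and 3 were not analysed here for want of a probe set with their symbol alone. CXCL1, CXCL8, ICAM1 and NFKBIA rose. Under the scan date block IL1B (1.71 ± 0.20), IL6 (1.38 ± 0.16) and PTGS2 passed too, giving 7. PPARG (0.23 ± 0.16), HMGCS1 (0.15 ± 0.22) and SCD (-0.09 ± 0.19) did not pass with either block, and SCD stood at 0.05 with scan date.

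Effects found on the first scan date recurred in the final set. Taken alone, the 4 arrays of the first scan date gave 13 called probe sets by limma, all higher with AA, and each of these was higher in the final set by at least 1.41. The final set has array B as its only untreated array, so every change in that set rests on it. The run record of B also lists another fluidics protocol than those of C and D. Within that set AA and the recorded protocol therefore cannot be told apart, while arrays 1, 2, 3 and 4 share a protocol. Of the 100 probe sets with the smallest p on the first date, 83 had the same sign in the final set. The share over all tested probe sets was 54.3%. The highest of 10000 random draws of 100 probe sets was 72 (permutation p = 1e-04, the smallest these draws can give). The draws treat probe sets as independent, which they are not, so this p does not measure recurrence over arrays. Over all probe sets, which are not independent replicates, the log2 changes of both dates had Pearson r = 0.23. limma's interaction between AA and title set called 0 probe sets (585 at an unadjusted p under 0.05, smallest adjusted p = 0.437), a test that rests on array B, the only untreated array of the final set. Between the title sets themselves 2848 probe sets differed, 1303 higher and 1545 lower in the final set. That count fell to 29 without array B and rose to 5391 without array 1a.

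**Figure D4:**
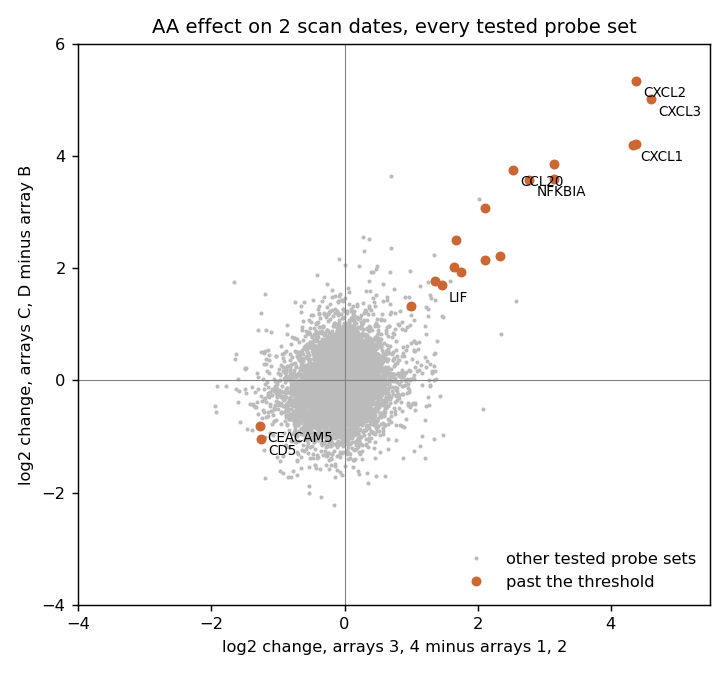
Log2 change with AA of every tested probe set on the first scan date (arrays 3 and 4 minus 1 and 2, horizontal) and in the final set (arrays C and D minus B, vertical). The 19 probe sets past the threshold over all 8 arrays are filled circles, 17 in the upper right quadrant and 2 in the lower left.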

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

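Tests of leukocytes, handling time and scaling for the NF-kB list, of recurrence across dates, and of splits within scan dates were chosen only after the result was seen. The counts over splits of the 8 arrays were planned.

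Of 246 groups of 4 arrays examined, 6 had 1 array far from the others, where chance gives about 12.3, and no array had more than 2 of them. The number is the gap to the nearest array over the group's range. PLAU was higher on array 1a than on the other untreated arrays (0.835), and SEMA6A also stood apart on array 1a (0.840). AJAP1 stood apart on array 3 among the AA arrays (0.899) and CREM on array D (0.847). The ratio of 5' to 3' ACTB signal, a measure of RNA integrity, stood apart on array C among the AA arrays (0.857), where it was 1.12. The mean of the endothelial list stood apart on array B among the untreated (0.837).

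The rise of NF-kB target genes with AA was weighed against 3 technical explanations. Leukocytes in the AA cultures would raise leukocyte markers, but that list's mean change was -0.318 ± 0.11 (SE). Its brightest member LCP1, with a signal of 1007, changed by 0.06. Which cells gave that signal was not tested, so LCP1 alone does not speak to added leukocytes. Scaling would move genes of the same signal alike, but the NF-kB list rose by 1.58 ± 0.11 (SE) more than other genes of the same untreated signal. Handling and 2 h in fresh medium stay open and cannot be told apart from AA, because 0 untreated arrays are labelled with 2 h. Arrays 1, 1a and 2 are titled 0 hr and array B, on which the final set rests, names no time in its title. The effect of AA itself, which the design names, also stays open as a hypothesis.

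The number of called probe sets was set against other splits of the 8 arrays into 4 and 4. As many were called in 2 of 35 splits, the real one with 19 included, so this count does not exclude chance. The other set arrays 1, 2, 3 and 4 against 1a, B, C and D and called 1667. B, C and D fall on the same side there, so the title set block absorbs them. The contrast left is array 1a against arrays 1, 2, 3 and 4. It points to a structure of the samples but rests on array 1a. The next largest called 4. Blocked by scan date, the real grouping called 31, and the other 17 ways of assigning groups within dates called 0, though 18 assignments are too few for a share under 0.05. For the gene lists, 14 of 35 splits called as many as the real 10 (highest other 14), so chance is not excluded for that count. The scan date block called 5 lists. For the final against the numbered arrays, the real split alone of 56 gave as many as 2848 (highest other 4). That share, 1 of 56, is under 0.05 and the smallest these splits can give. The final arrays also share a scan date and chip lot, which the splits cannot separate from the title set. Without array B the count was 29.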

How the results depend on the processing

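Scan date as a block and the first scan date alone were chosen after seeing the data; the other settings were fixed before. The NF-kB list kept its direction and its call under every setting run, with means from 1.36 (no filter) to 1.80 (floor of 200), and from 1.498 to 1.664 leaving out 1 array. Apart from the settings of estimated correlation and fry, these calls used the preset correlation of 0.01. The list's estimated correlation was 0.11, so those calls say little beyond the means. None of the 13 named genes past the threshold changed sign in a setting in which it was tested; 3 were not tested with a floor of 200 and 2 not as deposited. No paired analysis was possible because the untreated and AA arrays share no replicate numbers. The interaction was 0 in every setting in which it was run; it was not run without array B, for 1 title set or scan date alone, or under another block. Dim probe sets lie near the offset, which limits what can be said of CD5, CEACAM5 and COQ4.

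The 19 called probe sets became 10 with no block, 37 with array weights, 33 with arrays 1 and 1a averaged, 9 in the numbered and 11 in the final set alone (fewer arrays), and 31 with scan date as a block; leaving out 1 array gave 12 (without B) to 31 (without 1a). The 10 called lists became 3 with no block, 6 with weights, 5 in the final set, 5 with scan date, 1 with estimated correlation and 1 with fry, and 5 (without 1a) to 13 (without 1) leaving out 1 array. The 4 panel genes became 7 with weights, averaging or scan date, and 4 to 7 leaving out 1 array. The 2848 probe sets between title sets became 9529 as deposited (the scaling targets differ), 1681 with no filter, 5959 with weights and 4567 with averaging, and 29 to 5391 leaving out 1 array. Apart from fewer arrays and the scaling targets, the cause was not tested.

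Signs reversed only for changes that did not pass or, for 3 lists, that lost their call. In the final set alone SCD was 0.0976, TNF 0.102, MYC -0.117, CPT1A -0.163, ANGPTL4 -0.400, ACACA 0.0227, GINS2 0.190, CCNB2 0.0782, the S-phase list 0.0949 and the mitosis list 0.0277. On the first scan date alone SCD was 0.0222, MVK 0.0506, SLC7A11 -0.0355, RPL3 0.0367, RPL7 0.0431, KDR -0.201 and ENG -0.0200. In the numbered set RPL7 was 0.0545 and ENG -0.104. With scan date as a block SCD was 0.0523 and TNF 0.0356. With no block SCD was 0.0621, the S-phase list 0.00496, the mitosis list 0.0130 and the interferon list -0.0257. ANGPTL4 was -0.0290 as deposited and -0.0320 with an offset of 100, and TNF 0.0399 with array weights. Leaving out 1 array, SCD ranged from -0.198 to 0.0523, TNF from -0.368 to 0.0356, MYC from -0.0492 to 0.383, CPT1A from -0.165 to 0.232, ANGPTL4 from -0.188 to 0.252, RPL7 from -0.407 to 0.0545 and ENG from -0.104 to 0.359.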

Other observations

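Among the tests here, that of array scaling by quantile normalization was planned and those of genes of the same signal, of chip lot and scanner, of RNA integrity, of leukocytes, of array 1a and of recurrence were chosen only after the result was seen.

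Arrays 1, 2, 3 and 4, scanned on one date, differed widely from array 1a and the final arrays, whatever their group. Antiviral genes that interferons induce led the difference. RSAD2 had a mean signal of 7609 ± 1007 on those 4 arrays and 50.8 ± 40.6 on the other 4 (SD), IFI27 12847 ± 286 against 148 ± 141, and MX1 13595 ± 1835 against 510 ± 47.8. All 26 measured interferon genes were higher on the 4 arrays, by 3.55 on average on the log2 scale, and 17 of the 30 genes with the largest increases there belonged to that list. Some stress genes, picked from the top of this ranking, went the same way: ATF3 was higher by 3.32, GDF15 by 3.31, DDIT3 by 2.94 and NUPR1 by 3.06, and of the fixed stress lists the metallothioneins differed by 1.78 and ATF4 and unfolded protein genes by 0.895, but heat shock genes by -0.108 and NRF2 targets by -0.0598.

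Genes of dividing cells were lower on the same 4 arrays. RRM2, a subunit of ribonucleotide reductase, had a mean signal of 1089 ± 97.8 against 6710 ± 1554 on the other 4 (SD), TOP2A 251 ± 66.9 against 1486 ± 524, and BIRC5 659 ± 92.8 against 4063 ± 551. The mean of the mitosis list differed by -1.36 and that of S phase by -1.17. SPARC (94.1 against 1556) and FABP4, a carrier of fatty acids (357 against 3922), were also far lower.

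Array scaling may shift genes of like signal together, but the interferon list differed by 3.29 more than other genes of the same signal on the other arrays (SD between arrays up to 0.25), and by 3.52 after quantile normalization. Chip lot, scanner, wash protocol and scaling target were the same for array 1a, whose list mean differed from the 4 arrays by -3.13. Leukocytes in those cultures would raise their own markers by a like amount, and the leukocyte list differed by 0.304, with a spread (SD) of up to 0.328 between arrays. RNA integrity also went with scan date. The 5' to 3' ratio of GAPDH was 0.954 to 1.14 on the 4 arrays and 1.19 to 1.43 on the others, though that of ACTB overlapped. The mean log2 difference of the GAPDH ratio was -0.337, and the interferon list exceeded genes of the same signal by 3.29. The first is a ratio within 1 gene and the second a level, so their sizes are not comparable. RNA integrity by this ratio separates the same arrays and cannot be told apart from scan date here. A different state of the cultures, such as density, passage or an infection, stays open and was not tested, and no group of the design gives a biological explanation.

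Array 1a is the link between this difference and the AA comparison, since it counts as an untreated array of the numbered set. Blocked by scan date, the interferon list's mean change with AA went from 0.795 to 0.140 and its call ended, so array 1a may account for most of it (adjusted p = 0.0671 by camera, SE over arrays 0.85 before and 0.02 after). The immediate-early list went from 0.361 to 0.276 and was still called at the preset correlation but not at an estimated one (adjusted p = 0.0514), so array 1a does not account for its whole mean, while the call itself depends on the correlation assumed.

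The chance that the AA effects recur on separate arrays was tested by direction. Of the 100 probe sets with the smallest p on the first scan date, 83 had the same sign in the final set. Probe sets are not independent, and array B, the only untreated array of that set, has another recorded fluidics protocol than C and D. The count goes with a direction that recurs across dates but does not measure recurrence over arrays. IL1B, IL6 and IRF1 did not pass with the title set block. With scan date as the block they did, with changes of 1.71, 1.38 and 1.40. Leaving out array 1a gives the same values by construction, since that block gives it no weight. The genes also passed with array weights or arrays 1 and 1a averaged.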
